A study of Bos taurus with 32 samples.

How the data were processed

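Total RNA of bovine oocytes and in vitro produced embryos was labelled for m6A with an allyl group and sequenced. Per the labels' protocols, oocytes came from follicles of 3 to 5 mm, were matured for 22 to 23 h, fertilised for 18 h and cultured until day 7.5. The samples form 16 groups, 8 stages by 2 arms, with 2 replicates each. Trimmomatic 0.39 and STAR 2.5.3a are named in the submitters' processing notes. The site caller, the genome build, the annotation, and the way in which arms and replicates of a stage were combined are not given in the sources used here.

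The authors deposited a score for each adenosine and stage, with the chromosome, strand, gene, region and 5-base motif. The table is named for raw counts, but its values are not whole numbers, and its scale is not stated. Identical scores recur within a motif, with 21603 distinct pairs of motif and score over 53715 GV sites, and the highest GV score is 402. Each listed site has a score of at least 0.1 in at least 1 stage, and that minimum was used to call sites. A score of 0 can stand for an unmodified adenosine or for no estimate. Depth and RNA level are unknown, so a site can be missing at a stage because its transcript was little sequenced.

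The table has 65536 lines with its header, the row limit of an older spreadsheet format, and its order shows which part is held. It opens with 729 sites of large-subunit ribosomal protein genes. Then follow 29227 sites of the minus and 30889 of the plus strand called at GV, and 4690 of the minus strand called at MII and not at GV, which run from chromosome 10 to position 139251926 of chromosome 1. Within each part chromosomes follow 1 order and positions increase. Sites called first after MII, outside the ribosomal genes, were not analysed here. GV and MII were therefore compared on the minus strand of chromosomes 10 to 19, and later stages only at GV-called sites.

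Of 57079 sites whose symbol has a protein-coding RefSeq entry, 97.9% lie inside the span of that gene in ARS-UCD2.0, which served only as a check of names. A gene is missing for 7.03% of all sites. Each column was taken as a pooled value of its stage, and 0 columns of sample values were left without a stage. The values do not separate input from treated libraries, so that comparison was not analysed here.

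The designs fixed before the data were examined assumed read counts with replicates and tests per gene. Scores without replicates do not allow them, so no p-value is given. The rule for named genes was adapted after the structure of the table and some values had been seen. Protein-coding genes with a symbol and at least 10 GV-called sites were ranked by the number of called sites at the later stage minus the number expected from the earlier stage and the ratio of both totals. The highest 5 and lowest 5 were named for each adjacent pair of stages and the highest 10 and lowest 10 for GV to blastocyst. Members of the 20 fixed gene lists were added as examples, and these, the ribosomal genes and the top GV genes were chosen with their values in view. From the sites called in every stage, the 5 highest and 5 lowest log2 ratios of blastocyst to GV score in protein-coding genes with a known region were listed, and 5 of the 10, chosen with their values in view, are given. Some genes that these rules name are not reported here.

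For each list, the percentage of its GV-called sites called at a stage was ranked among 10000 random lists matched on GV-called sites per gene. Shares of sites have exact Clopper-Pearson intervals at 95%, and neighbouring sites of a transcript are not independent. Scores at shared sites were compared by the median log2 ratio. Intervals of ratios in the closing section come from order statistics or from 1000 resamples of sites or genes. The calculations were tested on a simulated table of 65535 sites, where 10 of 10 checks passed. A list planted at 30% was recovered at 29.4%, and 6% of 200 unchanged lists lay outside the central 95%. Simulated sites were called independently of their gene and the unchanged lists were drawn at random. The simulation therefore checks the arithmetic and cannot show how the percentiles behave where calls cluster by gene. Alternatives were a score of at least 0.2, any score above 0, DRACH motifs, protein-coding genes, a window extended to chromosome 1, each list without its gene with most sites, and a histone list without H3C6 and H1-5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.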

Results

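Positions of N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, were mapped in bovine oocytes and preimplantation embryos by m6A-SAC-seq. In this assay m6A is labelled with an allyl group and is read as a mutation after reverse transcription. The labels describe 32 libraries over 8 stages, with an input and a treated arm of 2 replicates each, and 200 cells per stage and replicate. If single blastomeres were counted, 200 cells come from fewer embryos at later stages. The amount of RNA may therefore differ by stage, which cannot be told apart from stage itself. The stages were immature germinal vesicle (GV) oocytes, mature metaphase II (MII) oocytes, 2-cell, 4-cell, 8-cell and 16-cell embryos, morulae and blastocysts. The table analysed here lists 65535 adenosines with 1 score per stage, so no value has a replicate error and the read depth behind each score is unknown. A site was counted as called at a stage when its score was at least 0.1, and exact 95% binomial intervals cover the counting of sites only.

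GV oocytes carried 60417 called sites, 55241 of them in 6464 protein-coding genes. CENPF, a kinetochore protein of dividing cells, had the most with 161 sites, followed by PLEKHG1 with 109, the spectrins SPTAN1 with 93 and SPTBN1 with 83, and AKAP11 and TRIP12 with 79 each. The median gene had 5 sites, 1270 genes had 1 site and 1953 genes had at least 10. Coding sequence held 71.0% of the sites with a known region and 3' untranslated regions held 22.9%, while 5' untranslated regions held 2.77% and introns 3.27%. Median scores were 0.205 in coding sequence (quartiles 0.147 and 0.327) and 0.248 in 3' untranslated regions (quartiles 0.163 and 0.465).

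The consensus m6A motif DRACH surrounded 34.2% of the GV sites with a listed motif, and the median score was 0.314 at these sites and 0.190 at the others. The error rate of the calls is unknown, so how many of the 35344 sites outside DRACH carry m6A cannot be told. Counts by gene and stage include these sites unless stated otherwise. By the 3 central bases, GAC made up 39.4% of sites, GAT 30.7%, GAG 13.1% and GAA 12.5%. AGATG was the most frequent 5-base motif with 4621 sites and a median score of 0.208. Among DRACH motifs AGACA had only 7 sites, against 4028 at AGACT and 2898 at AGACC, for a reason that is not known. Motif counts, DRACH shares and results at DRACH motifs alone may therefore depend on how sites of each motif were called. GGACA sites had a median score of 1.45, and 60.7% of them lay above 1, against a median of 0.435 at GGACT. The scores therefore cannot be read as a fraction of modified molecules across motifs.

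From GV to MII the comparison asks how the map differs after meiotic maturation. Both stages can be compared in full on the minus strand of chromosomes 10 to 19, where the ordering of the table shows both lists in full apart from ribosomal protein genes. In this window 11562 sites were called at GV and 8262 at MII, with 3873 called at both, 7689 at GV only and 4389 at MII only. The shared sites made up 33.5% of GV sites (interval 32.6 to 34.4) and 46.9% of MII sites. Their median log2 ratio of MII to GV score was -0.12 (quartiles -0.49 and 0.26), with 41.3% of them higher at MII. DRACH motifs were found at 46.9% of shared sites, 29.4% of GV-only sites and 29.6% of MII-only sites.

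Within the window, MII had more called sites than the overall ratio of 0.715 gives for ERN1 (ENSBTAG00000016799, chromosome 19), a sensor of unfolded proteins in the endoplasmic reticulum, with 16 sites at GV and 27 at MII. PRR14L had 22 and 30 sites, TRIP4 17 and 23, PCMTD2 13 and 20, and the glycolytic enzyme gene PKM 10 and 18. Fewer sites at MII were found for RANBP2, a nuclear pore protein (33 at GV and 10 at MII), and for PRDM2, a chromatin regulator (51 and 24). The endoplasmic reticulum chaperone gene HSPA5 had 21 and 5 sites, the integrin adaptor FERMT2 50 and 26, and the Golgi protein COG6 21 and 6. The G2/M cell cycle genes listed in the window had 216 sites at GV and 159 at MII, and the oocyte and maternal-effect genes 84 and 55.

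Over all chromosomes, 20625 of the GV-called sites were called again at MII, which is 34.1% (interval 33.8 to 34.5). PLEKHG1 kept 58 of 109 sites, LEO1, a subunit of a transcription elongation complex, 39 of 64, and the histone methyltransferase gene KMT2C 41 of 71. FMNL2 kept 39 of 66 and CTNND1, which encodes a catenin of cell junctions, 37 of 62. Few sites were called again in the deubiquitinase gene USP9X (8 of 53), RNF20 (2 of 31), TRRAP (3 of 33), the splicing factor gene SF3B1 (1 of 25) and ITSN2 (3 of 30). After MII only sites that were also called at GV are listed in full, so each later stage is described at those sites and its own new sites were not analysed here.

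**Figure D1:**
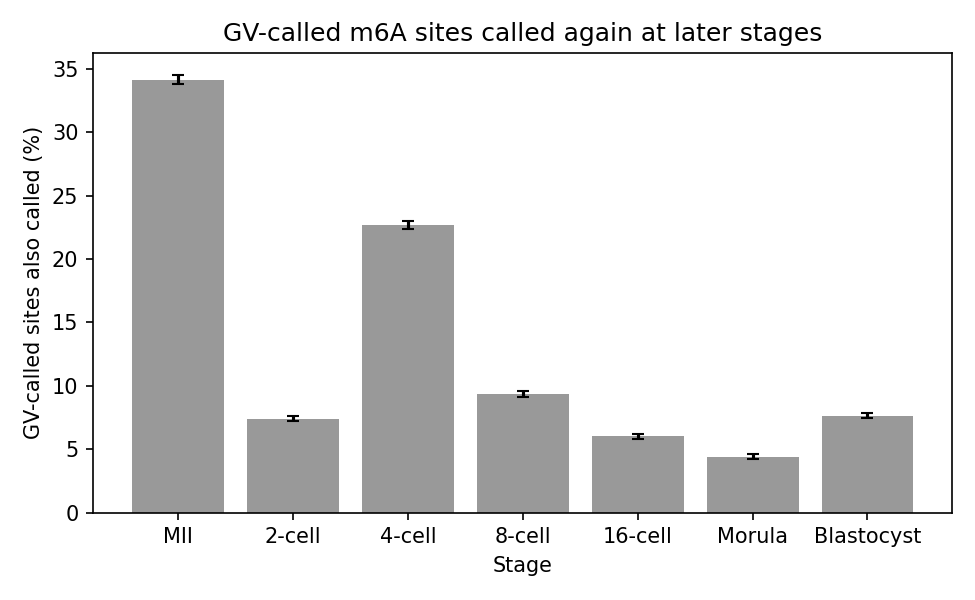
Percentage of the 60417 GV-called sites that were also called at each later stage, with exact 95% binomial intervals over sites as error bars. MII is the highest bar at 34.1% and the 4-cell stage is at 22.7%, between 7.39% at the 2-cell and 9.32% at the 8-cell stage.

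At the 2-cell stage 4467 GV-called sites were called, 7.39% (interval 7.19 to 7.61), against 20625 at MII. Counted at GV-called sites only, ANKRD17 had 33 called sites at MII and 24 at the 2-cell stage, and CTNND1 had 37 and 24. The oocyte growth factor gene BMP15 had 24 and 21, the homeobox gene MSX1 13 and 16, and RGS16, a regulator of G protein signalling, 18 and 17. No 2-cell call was found in KMT2C (41 at MII), WDR19 (25), the cullin regulator gene CAND1 (24) or ZNF215 (24), and NHSL1 had 33 and 2. MII and the 2-cell stage shared 3219 sites, against 1525 for independent lists of these sizes, and the median log2 ratio of 2-cell to MII score at the shared sites was 0.29.

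The 4-cell stage had 13701 called GV sites, 22.7% (interval 22.3 to 23.0), which is 3.07 times the 2-cell number. Sites were called at the 4-cell and hardly at the 2-cell stage in KMT2C (19 and 0), PLEKHA7 (16 and 0), NHSL1 (24 and 2), WDR26 (24 and 2) and the transcriptional corepressor gene NCOR1 (23 and 2). Numbers stayed closer together in CTNND1, with 24 sites at the 2-cell and 30 at the 4-cell stage, in BMP15 (21 and 22), MSX1 (16 and 11), LEO1 (20 and 25) and ANKRD17 (24 and 38). Both stages shared 2827 sites, while 1640 were called at the 2-cell and not at the 4-cell stage and 10874 the other way round. At the shared sites the median log2 ratio of 4-cell to 2-cell score was -0.35 (quartiles -0.83 and 0.07).

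By the 8-cell stage 5628 GV-called sites were called, 9.32% (interval 9.08 to 9.55). More sites than the overall ratio of 0.411 gives were called in the chaperone gene HSPA8, with 18 sites in 4-cell and 22 in 8-cell embryos, in its partner DNAJB1, with 24 and 21, and in the translation factor gene EIF4G2, with 12 and 17. BMP15 had 22 and 20 sites and HNRNPU, an RNA-binding protein of the nucleus, 15 and 17. Fewer than that ratio gives were called in PLEKHG1, with 45 and 6 sites, CENPF (34 and 3), SPTAN1 (46 and 10), NHSL1 (24 and 1) and NCOR1 (23 and 0). The stages shared 3593 sites, with a median log2 ratio of 8-cell to 4-cell score of 0.23.

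In 16-cell embryos 3632 GV-called sites were called, 6.01% (interval 5.82 to 6.20). HSPA8 had 22 sites at the 8-cell and 28 at the 16-cell stage, the elongation factor gene EEF2 13 and 19, the chromatin reader gene BRD2 7 and 15, and the tubulin gene TUBA1B 10 and 15. CDH1, which encodes the adhesion protein E-cadherin, had 6 and 14. Sites were fewer in PHKA2 (18 and 0), DLG5 (17 and 1), ANKRD17 (19 and 3), GATAD2A (14 and 1) and RIOK3 (14 and 1). The shared sites numbered 1668, with a median log2 ratio of 0.08.

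Morulae had 2672 called GV sites, 4.42% (interval 4.26 to 4.59), the lowest percentage of the stages. The chaperone gene HSP90AA1 had 10 sites at the 16-cell stage and 19 in morulae, the junction gene CTNNA1 1 and 9, the actin crosslinker gene ACTN1 4 and 10, and GLUD1, a glutamate dehydrogenase gene, 0 and 7. ACCSL had 14 and 2 sites, KHSRP 18 and 5, DAG1 11 and 0, BRD2 15 and 3, and the amino acid transporter gene SLC1A5 13 and 2. These stages shared 1324 sites, with a median log2 ratio of 0.03.

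Blastocysts had 4613 called GV sites, 7.64% (interval 7.42 to 7.85), and shared 1652 of them with morulae. HSP90B1, a chaperone of the endoplasmic reticulum, had 1 site in morulae and 20 in blastocysts, and HMGCS1, an enzyme of sterol synthesis, 0 and 18. DAG1 had 0 and 15, the fatty acid activating enzyme gene ACSL3 4 and 20, and the splicing factor gene PRPF8 4 and 19. Below the overall ratio of 1.73 were C1QBP (11 and 6), 1 of the gene entries of the histone H3C6 (ENSBTAG00000055948, 11 and 6), the histone gene H1-5 (13 and 12), TUBA1B (13 and 13) and HSPA8 (22 and 29). The median log2 ratio at shared sites was -0.0045.

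Across the whole series, from GV to blastocyst, the chaperone genes HSPA8 and HSP90AA1 and the adhesion gene CDH1 kept the most sites beyond the overall percentage. HSPA8 kept 29 of 38 sites, HSP90AA1 25 of 38, CDH1 24 of 42, CTNNA1 23 of 46 and EIF4G2 23 of 39. The citrate synthase gene CS kept 22 of 36, the membrane linker gene EZR 21 of 26, ACSL3 20 of 35 and CTNND1 22 of 62. No blastocyst call was found among the GV sites of PLEKHG1 (109), SPTBN1 (83), DLG5 (71), SVIL (70), KIDINS220 (67), LEO1 (64), NLRP14 (64) and NHSL1 (63), while CENPF kept 1 of 161 and AKAP11 1 of 79. At the sites called in both stages the median log2 ratio of blastocyst to GV score was 0.19 (quartiles -0.19 and 0.63). GV-only sites numbered 31414, or 52.0% of those called at GV.

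Gene lists fixed before the data were examined were compared with 10000 random lists matched on GV-called sites per gene, as a description of these libraries. Of 119 pairs of list and stage, 21 lay above and 1 below the central 95% of the random lists, against 5.95 that chance gives on both sides together, and stages and lists are not independent. Cytosolic ribosomal protein genes kept 40.8% of 191 sites at MII (percentile 99.99) and 18.8% at the 4-cell stage (percentile 92.1). They were at 30.9% at the 8-cell, 51.8% at the 16-cell, 53.9% at the morula and 63.9% at the blastocyst stage, each at percentile 100.

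The 26 oocyte and maternal-effect genes with GV sites kept 56.2% of 429 sites at MII, 32.6% at the 2-cell, 49.9% at the 4-cell and 31.7% at the 8-cell stage, each at percentile 100 of the random lists. BMP15 had 28 sites at GV and 20 at the 8-cell stage, and BTG4, an adaptor of mRNA decay, had 24 and 13. WEE2, an oocyte kinase, had 29 and 8, and NLRP5, a maternal-effect gene, had 33 and 8. At the 16-cell stage the list was at 5.59% (percentile 53.0), with no call in WEE2 or NLRP5, and at the blastocyst stage at 0.699% (percentile 0.04). Cumulus and granulosa cell markers had 47 GV sites, 16 in the steroidogenic gene STAR and 14 in HAS2, and 38.3% of them were called at MII.

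Junction and cavitation genes serve the epithelium and fluid cavity of the blastocyst. They kept 42.4% of 198 sites at MII (percentile 66.5), 8.08% at the 2-cell (percentile 40.0), 23.2% at the 4-cell stage (percentile 20.6), 18.7% in morulae (percentile 99.7) and 40.4% in blastocysts (percentile 99.98). EZR and CDH1 carried 45 of the 80 blastocyst sites, and OCLN, a tight junction gene, kept 6 of 32. Nuclear-encoded oxidative phosphorylation genes kept 2.83% of 212 sites at the 2-cell stage (percentile 37.8), 53 of the sites in morulae and 35.8% in blastocysts, both at percentile 100. ATP5F1A, a subunit of ATP synthase, kept 11 of 22 in blastocysts, and COX6A1, a subunit of cytochrome c oxidase, 6 of 8.

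Stress and apoptosis genes kept 33.2% of 217 sites at the 8-cell, 32.3% at the 16-cell, 24.9% at the morula and 39.6% at the blastocyst stage, each at percentile 100. HSPA8 and HSP90AA1 held 54 of the 86 blastocyst sites, PRDX1, a peroxidase gene, kept 12 of 12, and HSPA5 had 1 called site in morulae and 11 in blastocysts. HSPH1 had no blastocyst call among 18 GV sites, MDM2 and GADD45A none among 9 each, DDIT3 none among 6 and BCL2L1 none among 5. The chaperone gene DNAJB1 kept 2 of 35. The percentage therefore came from a part of the list, mainly HSPA8, HSP90AA1, PRDX1 and HSPA5, and not from chaperone genes as a class. Sterol synthesis genes were at 0% in morulae and 26.0% of 96 sites in blastocysts (percentile 97.4), with 18 of the 25 sites in HMGCS1 and 5 in MSMO1, and at 15.6% (percentile 83.8) without HMGCS1. The 4 embryonic genome activation genes with GV sites kept 64.7% of 34 sites at MII (percentile 99.02) and 32.4% in morulae (percentile 99.2). RBBP7, a histone-binding protein, held 23 of the 34, and without it the list was at 45.5% (percentile 92.3) and 36.4% (percentile 98.5). In the pluripotency list SALL4 held 29 of 53 sites, and the list lay within the central 95% at each stage.

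G2/M cell cycle genes kept 12.3% of 481 sites at the 2-cell stage (percentile 92.9), and without CENPF the list was at 15.6% (percentile 99.4). AURKA, a spindle kinase, had 19 GV sites and 15 at the 2-cell stage, and CCNB1, a mitotic cyclin, 16 and 11. Maternal mRNA clearance genes kept 8.29% of 374 sites at the 2-cell stage (percentile 52.4) and 6.42% at the blastocyst stage (percentile 45.2), and 19 of those 24 blastocyst sites were in CNOT1, the scaffold of a deadenylase. Without CNOT1 the blastocyst value was 1.59% (percentile 1.45). DNA methylation and histone modification genes kept 10.1% of 476 sites in blastocysts (percentile 81.2), with 9 of 55 in the chromatin remodeller gene SMARCA5. Trophectoderm genes kept 21.1% of 38 sites in blastocysts (percentile 91.1), and 6.25% (percentile 66.9) without the gene with the most sites. The 3 sites of the hypoblast list were called at GV only. Blood cell and sperm lists had 0 GV-called sites, and mitochondrially encoded genes, whose chromosome is not among the 30 listed, were not analysed here.

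The genes that write, remove and bind m6A carried sites themselves. Writers had 75 GV-called sites, 23 in RBM15B, 18 in CBLL1, 9 in WTAP, 8 in VIRMA and 3 in METTL14, while METTL3 had no site in the table. They were called at 37.3% at MII, 5.33% at the 2-cell, 26.7% at the 4-cell and 4.00% at the blastocyst stage, at percentiles of 72.9, 52.2, 76.8 and 34.2. Of its 23 GV-called sites the demethylase gene ALKBH5 kept 10 at MII and 11 at the 2-cell stage. It kept 14 at the 4-cell and 2 at the blastocyst stage. With sites not called at GV counted as well, ALKBH5 had 16 called sites at MII. FTO, the other demethylase gene, had no site in the table. Readers had 114 GV sites, 39 of them in IGF2BP3, which kept 21 at MII, 9 at the 2-cell, 4 at the 8-cell and 0 at the 16-cell stage, and PRRC2A kept 3 of 23 in blastocysts.

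**Figure D2:**
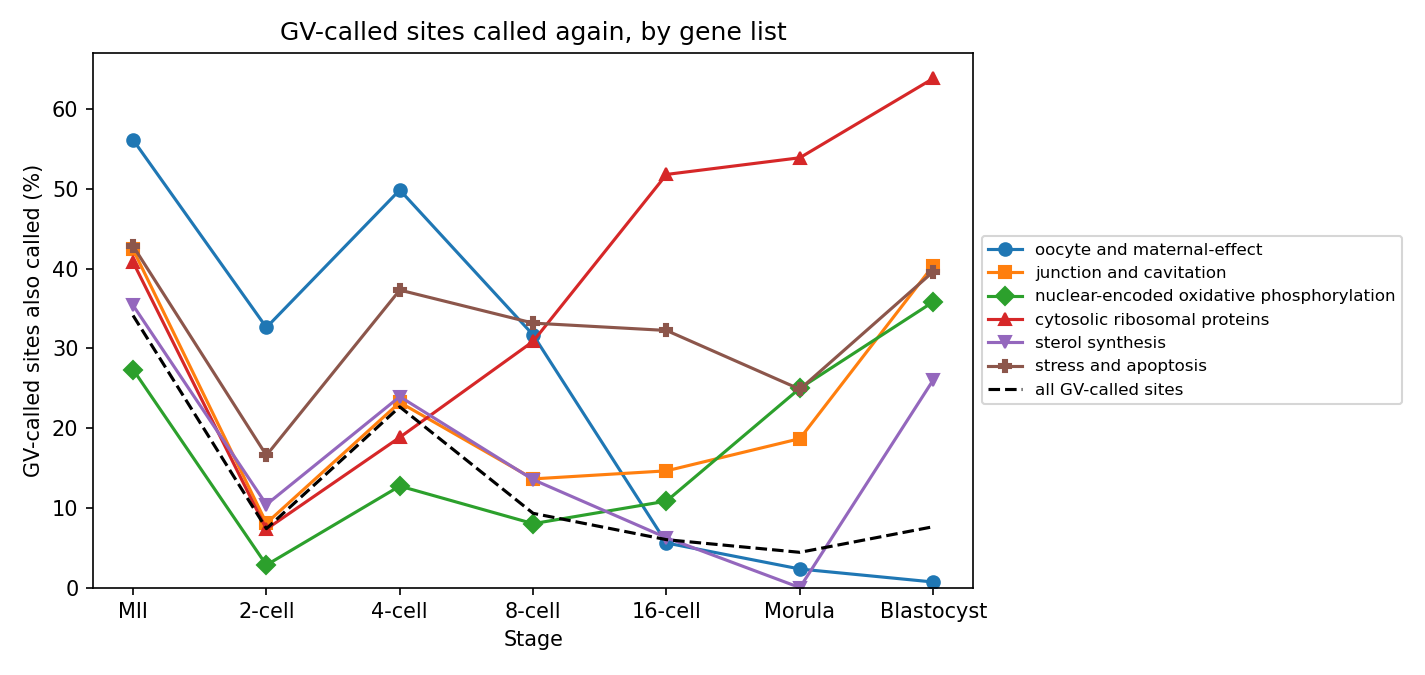
Percentage of GV-called sites called again at each later stage, for 6 gene lists as coloured lines and for all GV-called sites as a dashed line. Oocyte and maternal-effect genes go from 56.2% at MII to 0.699% in blastocysts, while cytosolic ribosomal protein genes reach 63.9%.

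Large-subunit ribosomal protein genes are listed for every stage regardless of GV calls, so their totals are not limited to GV-called sites. The read depth behind these totals is unknown at each stage. Genes of the cytosolic ribosome (RPL) had 185 called sites at GV, 130 at MII, 27 at the 2-cell, 62 at the 4-cell, 115 at the 8-cell, 185 at the 16-cell, 205 at the morula and 256 at the blastocyst stage. Genes of the mitochondrial ribosome (MRPL) had 116, 105, 15, 41, 24, 21, 26 and 26 in the same order. Of the 37 RPL genes, 25 had more sites in blastocysts than at GV, 6 had fewer and 6 had equal numbers, while of the 36 MRPL genes 4 had more, 26 fewer and 6 equal numbers. At GV-called sites alone, RPL genes kept 119 of 185 in blastocysts and MRPL genes 13 of 116, against 7.64% of all GV-called sites. The loss of MRPL sites was therefore not larger than that of GV-called sites in general. RPL22 had 1 site at GV and 11 in blastocysts and RPL14 had 3 and 11, while MRPL4 had 13 and 1 and MRPL44 9 and 0. With scores of at least 0.2 the RPL total was 67 at GV and 65 in blastocysts, so the higher RPL number came from scores between the 2 minimums, and the MRPL total was 59 and 26. At DRACH motifs alone RPL genes had 28 sites at GV and 44 in blastocysts, and MRPL genes 39 and 17. Small-subunit genes with RPS or MRPS symbols had 0 listed genes and were not analysed here. FAU, a small-subunit gene with another symbol, was counted only in the fixed list of cytosolic ribosomal proteins, with 5 GV and 4 blastocyst sites.

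**Figure D3:**
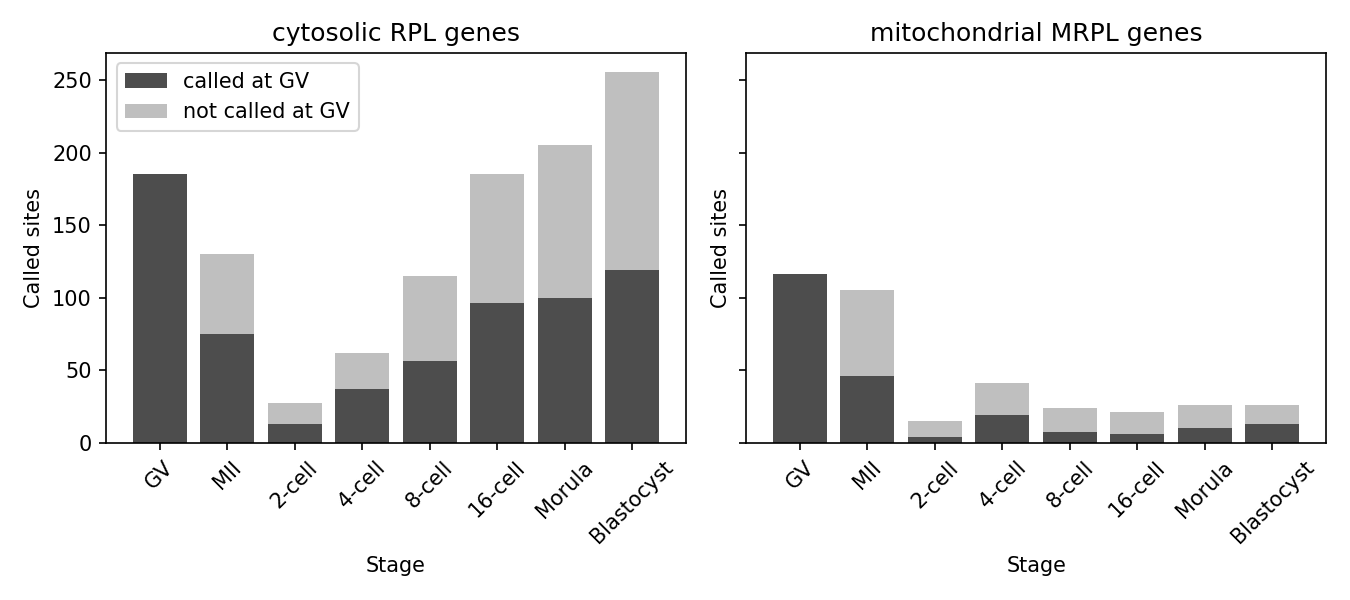
Called sites in cytosolic (left) and mitochondrial (right) large-subunit ribosomal protein genes by stage, split into sites also called at GV (dark) and not called at GV (light). Cytosolic genes reach 256 sites in blastocysts, 137 of them not called at GV, and mitochondrial genes have 26, but at scores of at least 0.2 the cytosolic total is 65 against 67 at GV and the mitochondrial total 26 against 59.

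In every stage 250 sites were called, 181 of them in 111 protein-coding genes and 45 in other annotated genes. The RNA of the signal recognition particle had 9 such sites, the translation factor gene EIF4A1 and the linker histone gene H1-5 7 each, and H3C6 and 5S ribosomal RNA 5 each. Reads from the near-identical copies of the histone and small RNA genes may be shared among them, so these sites are uncertain in their position. Median scores of the 250 sites lay between 0.206 at the 4-cell and 0.237 at the blastocyst stage.

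Among the 250, the coding site of CFL1, an actin-severing protein, at position 43974359 of chromosome 29 (motif AGATG) had a score of 0.224 at GV and 0.137 in blastocysts, with 0.113 at the 4-cell stage. The EEF2 coding site at 20034825 of chromosome 7 (GGACA) had 2.06 and 1.35, and between them ranged from 3.26 at the 2-cell to 0.834 at the 4-cell stage. Higher in blastocysts was the 3' untranslated site of SUPT5H, a transcription elongation factor gene, at 49158830 of chromosome 18 (GGACT), with 0.486 and 1.03. The coding site of RPIA at 47385898 of chromosome 11 (GAACC) had 2.15 and 4.54, with 1.86 at the 2-cell and 4.79 at the 16-cell stage, and that of ABCF2 at 113789719 of chromosome 4 (AGATG) 0.580 and 1.11. The genome build of these positions is not given in the sources used here.

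**Figure D4:**
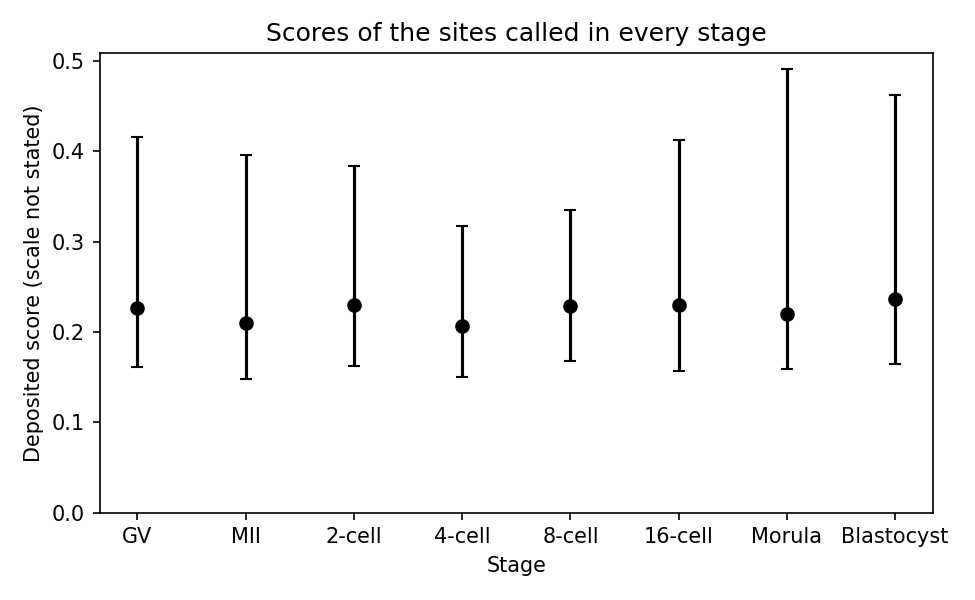
Median score of the 250 sites called in every stage, with bars from the lower to the upper quartile over sites and the deposited score on the vertical axis. All medians lie between 0.206 and 0.237.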

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

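The tests of a uniform score difference, of shallower 2-cell data, of transcript loss, of a motif-specific scale, of the score minimum for the mitochondrial genes and of read numbers on ribosomal transcripts were chosen after the results they measure had been seen.

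GV oocytes had 4356 called sites in no annotated gene, 7.21% of their total, and the gene comparisons did not use them. Over the whole table such sites formed 1443 groups with gaps of at most 10000 bases on a strand, and 81 groups with at least 10 sites held 1320 sites. One group of 38 sites lay on the minus strand of chromosome 4 from 46698562 to 46704287, between listed sites of SRPK2 and ATXN7L1, with 17 called at MII, 11 at the 4-cell and 0 at the blastocyst stage. Another of 36 sites lay on the plus strand of chromosome 19 from 39039562 to 39045117, between SOCS7 and EPOP, with 16, 13 and 0. Unannotated ends of neighbouring transcripts or genes were not tested as their origin.

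GV-called sites were called at 7.39% in 2-cell and 22.7% in 4-cell embryos, with KMT2C at 0 and 19 sites. A lower score in 2-cell embryos stays open. At 600 sites with a GV score of at least 0.5 called at both stages the median log2 ratio of 2-cell to 4-cell score was 0.29 (interval 0.20 to 0.35), but 1958 such sites called at the 4-cell and not at the 2-cell stage cannot enter it. Shallower 2-cell data may contribute, since scores between 0 and 0.1 were 0.504 times as frequent among non-zero scores as at the 4-cell stage (interval 0.428 to 0.592). Loss and return of the transcripts cannot be told apart from this, because RNA levels are not in the table, and the 1640 sites called at the 2-cell and not at the 4-cell stage decide neither. Developmental stage itself stays open as an untested biological difference.

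GGACA sites often scored above 1. Such scores were not particular to GGACA. At GV 73.4% of 143 GAACC and 89.5% of 76 GTAGC sites also lay above 1, against 0.065% of AGATG sites. A motif-specific scale is a candidate explanation, since the median GGACA score was at least 3.03 times that of the other GGAC motifs in all 8 stages, with the lowest ratio at the 4-cell stage (interval 2.76 to 3.25). A set of strongly modified transcripts stays open. The median score of the other motifs was 0.208 in the 1117 genes with a GGACA score above 1. It was 0.172 in the 498 genes whose GGACA scores were all 1 or lower, a ratio of 1.21 (interval 1.18 to 1.24). Both medians lay close to the score minimum for a call, which can compress their ratio, so the test cannot decide. No biological explanation by stage was tested.

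RPL genes had 185 sites at GV and 256 in blastocysts, and MRPL genes 116 and 26. The lower MRPL number was not particular to these genes, since 13 of their 116 GV-called sites were called in blastocysts, against 7.64% of all GV-called sites. A higher score at the same RPL sites stays open, because the 119 sites called at both stages, with a median log2 ratio of -0.085 (interval -0.17 to 0.01), leave out the 137 blastocyst sites not called at GV. The score minimum stays open for RPL: with any score above 0 the product of both log2 ratios was -0.988, with 236 and 317 RPL and 130 and 26 MRPL sites, but at 0.2 RPL sites numbered 67 and 65. It was argued against for MRPL, with 59 and 26 sites at 0.2 and a highest log2 ratio of -1.18 over the 3 minimums. Read numbers on these transcripts cannot be told apart from a difference in modification, because depth is not in the table. The 19.2% of non-zero blastocyst RPL scores under 0.1, against 21.6% at GV, decide neither. Of non-zero MRPL scores, 0% were under 0.1 in blastocysts and 10.8% at GV, with median scores of 0.530 and 0.203 at called sites. Fewer reads on MRPL transcripts in blastocysts may therefore contribute. A biological difference between oocyte and blastocyst stays open and untested.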

How the results depend on the processing

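All alternatives reported here were chosen after the data had been seen. No paired analysis was possible because the table has 1 value per stage and no replicates. The alternatives planned for counts were not run, since the table holds scores: other tests and size factors, filters on counts, thinning, replicate blocks, other sets of libraries, and leaving out libraries or stages.

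Scores of at least 0.2 gave 33374 GV-called sites, and 30.0%, 6.30%, 17.8%, 7.97%, 5.68%, 3.80% and 6.86% of them were called at the 7 later stages, from MII to blastocyst in order of development. The window then had 2015 shared, 4557 GV-only and 2711 MII-only sites and a median log2 ratio of -0.16, and 87 sites were called in every stage. RPL genes had 67 sites at GV, 14 at the 2-cell and 65 at the blastocyst stage, and MRPL genes 59 at GV and 9 at the 2-cell stage.

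With any score above 0 the percentages, in the same order, were 39.3%, 7.88%, 25.7%, 9.98%, 6.47%, 4.94% and 8.43%, and sites that never reach 0.1 are not listed. The other 12 results stayed within 1.5 times or within their interval.

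DRACH motifs alone gave 18371 GV-called sites and 45.3%, 8.67%, 25.8%, 10.97%, 7.69%, 5.32% and 9.09% in the same order. The window had 1670 shared, 2023 GV-only and 1178 MII-only sites and a median log2 ratio of -0.21, and 79 sites were called in every stage. RPL genes had 28, 4 and 44 sites at the GV, 2-cell and blastocyst stage, and MRPL genes 39, 3 and 17. The smaller counts under both stricter settings follow from fewer sites entering, and for the percentages the cause was not tested.

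Protein-coding genes alone moved 3 percentages past their intervals, to 34.6% at MII, 23.1% at the 4-cell and 4.20% at the morula stage, and left 16 results within limits. Extending the window to chromosome 1 left its 4 results within limits. The 2-cell percentage was below the 4-cell percentage at scores of at least 0.2, at any score above 0, at DRACH motifs and in protein-coding genes. Leaving out the gene with most sites moved 25 of 105 list percentages past their interval. Depth behind the scores is unknown, which limits every call of absence.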

Other observations

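The tests in this part, including the histone list and its test, were chosen after the data had been seen.

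Small nucleolar RNAs, which guide modification of ribosomal RNA, kept more of their GV-called sites late in the series than protein-coding genes did. Of 157 sites in 109 genes, 40.8% were called at MII, 14.0% at the 2-cell, 29.9% at the 4-cell, 55.4% at the 8-cell and 66.9% at the 16-cell stage. Blastocysts kept 66.9% of them (exact 95% interval 58.9 to 74.2), in 80 genes, while protein-coding genes kept 7.57% of theirs. The high percentage was not particular to this class. Small nuclear RNAs kept 56.9% of 51 sites in blastocysts and ribosomal RNAs 68.6% of 35, while long non-coding RNAs kept 8.01% of 487. SNORD12 kept 3 of 3 sites in blastocysts, SNORD87 3 of 3 and SNORD15 3 of 3. SCARNA2, a small RNA of Cajal bodies counted apart from the 157 sites, kept 4 of 4. SNORD36, with a pair of gene entries, kept 0 of 3 sites in one and 1 of 1 in the other. Many of these RNAs lie inside introns of other genes and have near-identical copies, so the reads behind them are uncertain in origin.

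Histone genes kept sites through every stage. Over 29 genes with 184 GV-called sites, 53.8% were called at MII, 38.6% at the 2-cell, 53.3% at the 8-cell and 37.5% at the blastocyst stage. H1-4 kept 7 of 8 sites in blastocysts and H1-2 6 of 8, while the oocyte linker histone H1-8 kept 5 of 11 at the 8-cell and 0 at the 16-cell stage. The list was drawn up because H3C6, counted over all entries of that symbol, and H1-5 had kept many sites, so its blastocyst percentage, at percentile 100 of 10000 random lists matched on sites per gene, restates that observation. Without these genes the other 27 kept 33.3% of 135 sites, at percentile 99.995, which argues against the number of sites per gene as the whole reason. This remains a hypothesis found and tested on the same data. Reads shared among near-identical histone copies and high transcript levels may contribute and were not tested.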
